A study of Mus musculus with 12 samples.

How the data were processed

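Bulk RNA sequencing of 12 libraries was analysed, 3 from each of 4 adipose depots of male C57BL/6J mice on a high-fat diet, all labelled as surgically denervated. Total RNA was depleted of ribosomal RNA and sequenced as single-end reads of 75 bp. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, quantified with RSEM 1.3.0 on GRCm38.p4 and tested with DESeq2 1.10.1. The aligner and the annotation release were not given in the sources used here. The deposited table of each library, per the file headers, holds the RSEM expected count of each gene, which is an estimated read count with no normalization between libraries. It also holds the deposited TPM, an abundance per transcript scaled by effective length, which was not used for the tests. The deposited effective length, in bases, was used for the length alternative alone. Each table held 47729 genes, of which 47224 Ensembl IDs were found in the GENCODE M21 annotation, the source of symbols and positions. Symbols matched for 847 of 848 memberships of the gene lists.

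Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 18942, and libraries were scaled by TMM factors between 0.846 and 1.14. Differences were tested with the edgeR quasi-likelihood F test, two-sided, in 1 model with a coefficient per depot over all 12 libraries, and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The biological coefficient of variation was 0.385. The 7 comparisons were BAT against the mean of the 3 white depots, BAT against each white depot, and the 3 pairs of white depots. R 4.3.3 was used throughout. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, in 4 comparisons, and again with a correlation estimated from the data. Of 49 lists, 48 had at least 3 tested members. List counts were also adjusted over the list alone. The gene lists, the tests, the rule for named genes and most alternatives were chosen before the data were examined.

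Named genes followed a rule with 4 parts. The first took up to 5 genes in each direction with the largest log2 fold change among those past the threshold, with at least 10 CPM in the higher group, with no overlap between the groups' libraries and with a proper symbol. The second took, for each list described, up to 4 members with the smallest p. The third always took Ucp1, Lep, Adipoq, Adrb3 and Th. The last treated lists of other cell types like the second and added the library with the highest value where 1 stood apart. Genes outside the rule are named as such.

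Total counts ranged from 12933516 to 21106554 per library, and 3 counts, taken as the floor, equal 0.134 to 0.227 CPM. Folds against a group at 0 use a floor of 3 counts over the group, and ratios over 1 to 3 counts carry 95% exact counting intervals. No molecular identifiers were described for the reads, so intervals and floors cover counting error only. The share of counts of the 13 mitochondrially encoded protein genes was compared by an exact permutation test.

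Alternatives tried were size factors by the RLE and upper-quartile methods, TMM without mitochondrially encoded and ribosomal RNA genes, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, an offset for transcript length, a log2 fold change of at least 1, and leaving out each library in turn. The score of a list in a library is the mean log2 CPM of its tested members. An adipocyte score as a covariate (the mean log2 CPM of the pan-adipocyte genes, a list not tested with it), leaving out the 2 libraries with the lowest adipocyte score (EWAT 1 and BAT 2) and leaving out the 2 RWAT libraries with the most muscle transcripts (RWAT 1 and RWAT 3) were chosen after seeing the data. The test was checked on simulated data with 200 changed genes in each comparison: at a 2-fold change 2% to 24% were recovered over the 7 comparisons, at 4-fold 48% to 62%, at 8-fold 76% to 86% and at 16-fold 78% to 94%. In these simulations edgeR made 3 to 11 false calls, DESeq2 34 to 58 and limma-voom 2 to 6, and camera found the 1 shifted list in each of 4 comparisons with 0 false calls. Simulated genes were drawn independently of one another. In the real data the estimated correlation within a list was, for example, 0.808 for interferon response and 0.896 for cell cycle genes. The simulation therefore does not show how often camera makes false calls on these lists. Deviations from the depot means were correlated between libraries with the same replicate number: all 3 pairs were over 0.1 between BAT and RWAT and in 0 of the other 5 pairs of depots, so the fits without the block were kept. No per-library table was left out.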

Results

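RNA abundance was measured in 12 libraries of adipose tissue from male C57BL/6J mice on a high-fat diet, 3 in each of 4 depots. The depots were interscapular brown (BAT), epididymal white (EWAT), inguinal white (IWAT) and retroperitoneal white fat (RWAT). All 12 libraries were labelled as surgically denervated, so the comparisons were between depots of denervated fat and the effect of denervation itself was not tested. The total expected counts were 19910001, 18285352 and 19589467 in BAT 1 to 3 and 19220276, 18930927 and 21106554 in EWAT 1 to 3. They were 18103404, 20457136 and 17064476 in IWAT 1 to 3 and 20798169, 19380639 and 12933516 in RWAT 1 to 3. The labels did not say that replicates came from separate animals, so the p-values measure only the spread between these samples. Levels are CPM, read counts scaled to library size, as mean ± SD with n = 3 libraries per depot (n = 9 for the white depots together), and log2 fold changes are given ± SE. Positions are on GRCm38.

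The first comparison asked how BAT differed from the white depots. Zic1 was higher in BAT, and 3 of 6 tested posterior homeobox genes were lower than in the mean of the white depots. Zic1, a transcription factor of the dorsal trunk lineage from which interscapular brown fat arises, stood at 12.5 ± 4.58 CPM in BAT and 0.285 ± 0.297 CPM in the white depots. The posterior homeobox genes Hoxa9, Hoxa10 and Hoxc10 stood at 0.107 ± 0.0546, 0.0178 ± 0.0308 and 0 CPM in BAT and 4.36 ± 4.34, 5.96 ± 7.30 and 4.99 ± 5.38 CPM in the white depots. Their sum was 0.971 to 1.38 CPM in the EWAT libraries, against 10.1 to 53.4 CPM in those of IWAT and RWAT, and between BAT and EWAT alone their edgeR BH-adjusted p were 0.284, 0.210 and 0.213. Ucp1, the uncoupling protein of brown adipocytes, was uneven within BAT and stood at 1489, 0.253 and 1.70 CPM in BAT 1 to 3.

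Between BAT and the mean of the white depots, edgeR called 10 of 18942 genes at a Benjamini-Hochberg (BH) adjusted p below 0.05, 7 higher and 3 lower in BAT. Zic1 (chromosome 9, 91358058 to 91365810) rose by a log2 fold change of 5.84 ± 0.41 (edgeR BH-adjusted p = 6.13e-05) and was higher in 3 of 3 BAT libraries than in any white library. Its neighbour Zic4 rose by 6.80 ± 0.73, Syndig1, a synapse protein gene, by 5.22 ± 0.64 and the secreted signal Wnt16 by 2.41 ± 0.31 (edgeR BH-adjusted p = 0.0231, 0.0101 and 0.0231). Tbx15, a T-box factor of adipose development, rose by 2.40 ± 0.31 (edgeR BH-adjusted p = 0.0231). Tbx15 stood at 19.7 ± 3.35 CPM in BAT, 21.2 ± 3.45 CPM in IWAT and 0.207 ± 0.0710 CPM in EWAT. Zic4, Syndig1, Wnt16 and Apol9a were chosen after their values were seen. Zic1 stayed past the threshold in all 25 alternatives run for it, with log2 fold changes between 5.50 and 6.68. The calls that ended among these 10 genes numbered 9 without BAT 1 or RWAT 3, 5 without BAT 3, 8 without EWAT 1, EWAT 2 or EWAT 3, 1 without IWAT 2 and 3 without RWAT 1 or RWAT 2 (edgeR BH-adjusted p 0.05004 to 0.235). By other alternatives the numbers were 8 without both RWAT 1 and RWAT 3, 5 with the adipocyte covariate, 7 with limma-voom, 6 with only the groups compared, 3 with the replicate number as a block and 1 with the length offset (BH-adjusted p 0.0519 to 1.00). The count was 1 without BAT 1, 251 without BAT 2, 4 without EWAT 1, 3 without EWAT 2, 3 without EWAT 3 and 2 without RWAT 3, 180 by DESeq2 and 4 by limma-voom, and, with sets of libraries left out after seeing the data, 208 without EWAT 1 and BAT 2 and 4 without RWAT 1 and RWAT 3.

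The posterior homeobox genes fell as a set in BAT, with 3 of 6 tested members lower over all genes and 5 adjusted over the list alone. The list had a median log2 fold change of -3.19 (camera BH-adjusted p = 3.94e-18, adjusted p = 0.00337 with an estimated correlation). That median was -2.0 without both RWAT 1 and RWAT 3, with 20444 genes tested. Of the 48 lists tested in this comparison, it alone was called with an estimated correlation, and its median over all 12 libraries was the same with Hoxc10 at its bound. Hoxa9 fell by a log2 fold change of 4.57 ± 0.64 and Hoxa10 by 6.95 ± 0.95 (edgeR BH-adjusted p = 0.0231 and 0.0231). Hoxa10 had 1 count in the BAT libraries together and 954 in the white libraries, a ratio of 319 with a 95% counting interval of 57.3 to 12612. Hoxc10 had 0 counts in BAT and 819 in white fat, which made it at least 91.4-fold lower from a floor of 3 counts over the group (edgeR BH-adjusted p = 0.0231). Hoxc9 had a log2 fold change of -1.82 ± 0.54 (edgeR BH-adjusted p = 0.404). The anterior and central homeobox lists were not called (camera BH-adjusted p = 0.0765 and 0.207), nor was the depot developmental list, with a median of 0.41 and a mean of -0.15 (camera BH-adjusted p = 0.746).

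The thermogenic list was called higher in BAT by camera (adjusted p = 0.581 with an estimated correlation), and BAT 1 stood apart from the other BAT libraries. Of the 23 thermogenic genes tested, edgeR called 0 over all genes, and 11 were higher adjusted over the list alone. DESeq2 called 2 and limma-voom 0, and 15 had an unadjusted edgeR p below 0.05. The list had a median log2 fold change of 1.5 (camera BH-adjusted p = 3.56e-07, adjusted p = 0.581 with an estimated correlation). That median was -0.065 without BAT 1 and 0.85 with limma-voom. The call ended without BAT 1 (camera BH-adjusted p = 0.530), against 3.21e-12 to 0.530 over its 24 alternatives with the preset correlation. Ucp1 had a log2 fold change of 8.41 ± 1.59, Cidea, a lipid droplet protein of brown adipocytes, 6.27 ± 1.28 and Cpt1b, which carries fatty acids into mitochondria, 4.77 ± 1.02 (edgeR BH-adjusted p = 0.112, 0.130 and 0.143). Cidea stood at 309, 0.558 and 2.30 CPM in BAT 1 to 3. The mean log2 CPM of the thermogenic list was 5.65, 1.81 and 2.50 in BAT 1 to 3, and up to 3.61 in a white library (IWAT 1). Of the 10 brown fat identity genes tested, Zic1 rose over all genes, and 4 were higher adjusted over the list alone. The list had a median log2 fold change of 0.93 (camera BH-adjusted p = 4.93e-06, adjusted p = 0.121 with an estimated correlation). It was 0.15 without BAT 1. Lhx8, a brown fat homeobox factor, stood at 7.96 to 10.6 CPM in BAT, 0 in EWAT and up to 3.92 in IWAT and RWAT (fitted log2 fold change 5.16 ± 0.81, no bound, edgeR BH-adjusted p = 0.0991).

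Camera also called the lists of mitochondrial fuel use higher in BAT with all 12 libraries (adjusted p = 0.874 for each with an estimated correlation), but neither without BAT 1, where both medians were negative. Of the 20 fatty acid oxidation genes tested, edgeR called 0 over all genes, and 1 was higher adjusted over the list alone. DESeq2 and limma-voom each called 0, and 5 had an unadjusted edgeR p below 0.05. The fatty acid oxidation genes had a median log2 fold change of 0.60 (camera BH-adjusted p = 5.55e-04, adjusted p = 0.874 with an estimated correlation). That median was -0.068 without BAT 1 and 0.96 without BAT 2. The call ended without BAT 1 (camera BH-adjusted p = 0.414), against 4.87e-10 to 0.414 over its 24 alternatives with the preset correlation. Of the 19 tricarboxylic acid cycle genes tested, edgeR called 0 over all genes, and 0 passed adjusted over the list alone. An unadjusted edgeR p below 0.05 was reached by 3, and DESeq2 called 0 and limma-voom 0. The tricarboxylic acid cycle genes had a median log2 fold change of 0.55 (camera BH-adjusted p = 2.98e-04, adjusted p = 0.874 with an estimated correlation). That median was -0.16 without BAT 1 and 0.87 without BAT 2. The call ended without BAT 1 (camera BH-adjusted p = 0.121), against 1.4e-09 to 0.121 over its 24 alternatives with the preset correlation. Acadvl, an acyl-CoA dehydrogenase, had a log2 fold change of 1.24 ± 0.44 (edgeR BH-adjusted p = 0.651). The mean log2 CPM of skeletal muscle genes, which also oxidise fuel, was 3.50 in BAT 1, 0.52 in BAT 2 and -0.0093 in BAT 3. The 13 mitochondrially encoded protein genes took 2.03% ± 1.32 of the counts in BAT (SD, n = 3) and 1.54% ± 0.423 in white fat (SD, n = 9). The difference of 0.488 points did not exceed the spread (two-sided exact permutation test, p = 0.332, 220 splits, smallest possible p 0.00455). Without BAT 1 the difference was -0.254 points, and without BAT 2 it was 1.01 points. The pan-adipocyte genes were not called between BAT and white fat (median log2 fold change 0.24, camera BH-adjusted p = 0.954, adjusted p = 0.980 with an estimated correlation). Camera's direction was down despite the positive median. The list was called higher without BAT 2 and lower without BAT 3 (medians 0.65 and -0.47, camera BH-adjusted p = 0.0218 and 0.0129).

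The interferon response and the T and natural killer cell lists were called higher in BAT by camera (adjusted p = 0.132 to 0.366 with an estimated correlation). The B cell list was not called (median log2 fold change -0.13, mean 0.12, camera BH-adjusted p = 0.557). Of the 19 interferon response genes tested, 1 rose over all genes, and 19 were higher adjusted over the list alone. The interferon response genes had a median log2 fold change of 1.85 (camera BH-adjusted p = 7.54e-35, adjusted p = 0.132 with an estimated correlation). That median was 1.21 without BAT 1. Ifi44, an interferon-induced gene, rose by 3.09 ± 0.40 (edgeR BH-adjusted p = 0.0231) and stood at 35.6 ± 35.6 CPM in BAT against 4.33 ± 1.38 CPM in white fat. Apol9a, a member of a pair of near-identical genes whose count is uncertain, rose by 2.21 ± 0.30 (edgeR BH-adjusted p = 0.0231). The ubiquitin-like Isg15 had a log2 fold change of 2.63 ± 0.42 and the antiviral enzyme Oas2 1.5 ± 0.25 (edgeR BH-adjusted p = 0.0773 and 0.0965). Ifi44 stood at 76.1, 9.43 and 21.2 CPM in BAT 1 to 3. Without BAT 1 the Ifi44 log2 fold change was 1.88 (edgeR BH-adjusted p = 0.0748, 1.02e-07 to 0.337 over its 25 alternatives, those with DESeq2 and limma-voom included). Of the 19 T and natural killer cell genes tested, edgeR called 0 over all genes, and 14 were higher adjusted over the list alone. The number was 14 at an unadjusted edgeR p below 0.05, 6 by DESeq2 and 0 by limma-voom. The T and natural killer cell genes had a median log2 fold change of 1.63 (camera BH-adjusted p = 1.05e-10, adjusted p = 0.366 with an estimated correlation). That median was 0.30 without BAT 1. Granzyme A, Gzma, had a log2 fold change of 2.99 ± 0.58, and Il2rb, a receptor of these cells, 2.52 ± 0.58 (edgeR BH-adjusted p = 0.117 and 0.168). The mean log2 CPM of this list was 3.17, 0.30 and 1.53 in BAT 1 to 3, and up to 1.16 in white libraries.

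The mesothelial list, which marks the lining of the body cavity, was called lower in BAT by camera (adjusted p = 0.136 with an estimated correlation). Its mean log2 CPM was -1.24 to -0.067 in BAT and near that in IWAT (-0.59 to 0.24) and RWAT 1 (-0.51), and higher in EWAT (2.20 to 3.60) and RWAT 2 and RWAT 3 (2.13 and 2.65). Of the 17 mesothelial genes tested, edgeR called 0 over all genes, and 6 were lower adjusted over the list alone. At an unadjusted p below 0.05 edgeR had 10, and DESeq2 called 5 and limma-voom 0. The mesothelial genes had a median log2 fold change of -2.20 (camera BH-adjusted p = 2.31e-17, adjusted p = 0.136 with an estimated correlation). All 17 members had negative log2 fold changes, among them Aldh1a2, a retinoic acid enzyme, at -1.69 ± 0.41 and mesothelin, Msln, at -4.43 ± 1.22 (edgeR BH-adjusted p = 0.193 and 0.298). The Schwann cell list was not called (median 0.055, camera BH-adjusted p = 0.776, direction down), but without BAT 1 it was called lower in BAT (median -0.34, camera BH-adjusted p = 0.00185, against 0.00185 to 0.978 over its 24 alternatives with the preset correlation). The sympathetic neuron list was not called, and its median and mean differed in sign (median -0.18, mean 0.11, camera BH-adjusted p = 0.969, adjusted p = 0.980 with an estimated correlation). Adrenergic receptor genes were not called either (median log2 fold change 0.67, camera BH-adjusted p = 0.248, adjusted p = 0.874 with an estimated correlation). Adrb1, a beta receptor for noradrenaline, had a log2 fold change of 1.2 ± 0.42 (edgeR BH-adjusted p = 0.620).

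**Figure D1:**
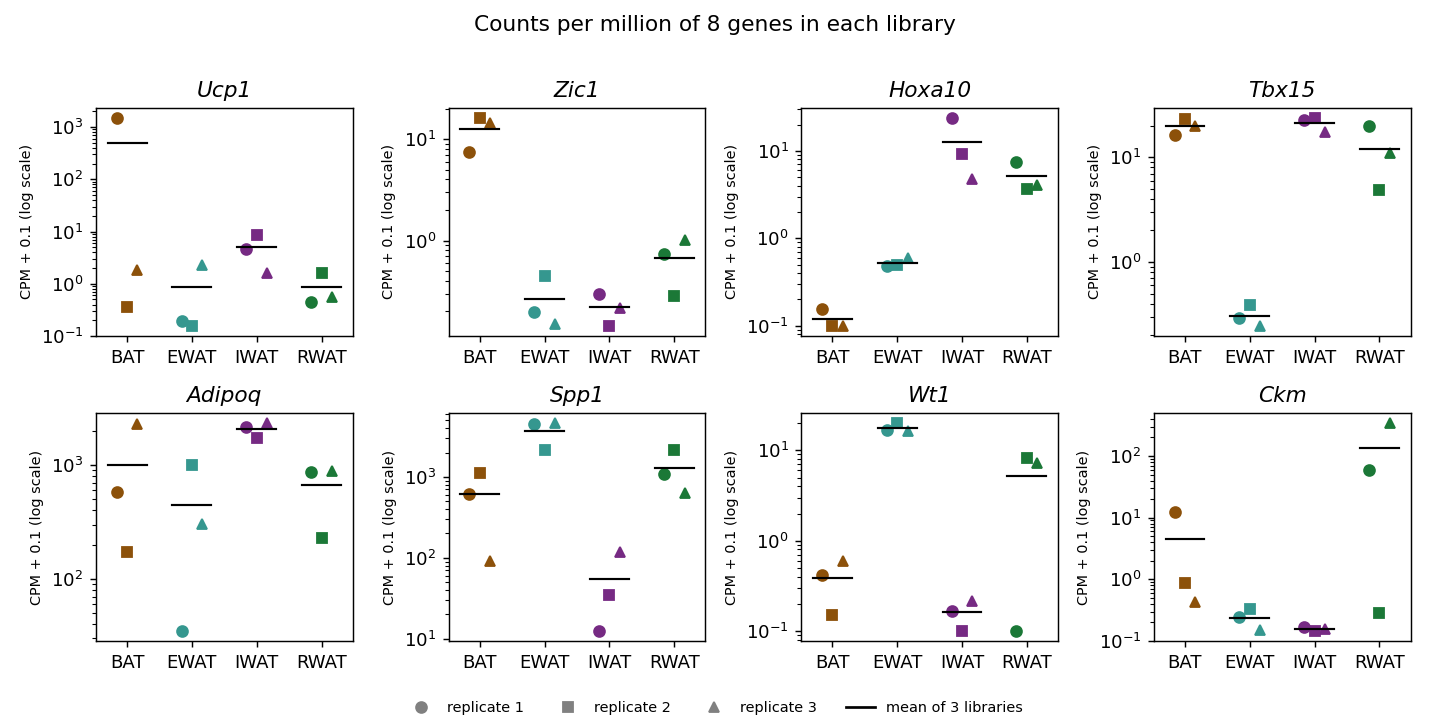
CPM plus 0.1, on a log axis, of 8 genes in each of the 12 libraries, with a marker shape for each replicate number and a bar for the mean of the 3 libraries of a depot. Ucp1 reaches 1489 CPM in BAT 1 alone, Zic1 stands apart in all 3 BAT libraries, Tbx15 is low in all 3 EWAT libraries, and Ckm is high in RWAT 1 and RWAT 3.

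BAT was also compared with each white depot, and edgeR called Zic1 higher in BAT in all 3 pairs. Against EWAT, edgeR called 27 genes, 17 higher and 10 lower in BAT. Tbx15 rose by a log2 fold change of 6.55 ± 0.55 and Zic1 by 6.28 ± 0.66 (edgeR BH-adjusted p = 0.00139 and 0.00314). The keratins Krt8 and Krt18, which mark mesothelium and other epithelia, had log2 fold changes of -5.38 ± 0.85 and -6.99 ± 1.04 and fell (edgeR BH-adjusted p = 0.0243 and 0.0146). Krt18 had 3 counts in BAT and 453 in EWAT, a ratio of 145 (95% counting interval 49.7 to 704). Against IWAT, edgeR called 5 genes. Zic1 rose by 6.73 ± 0.69 (edgeR BH-adjusted p = 0.00372). Hoxa9, at -6.20 ± 0.67, Hoxa10 and Hoxc10 fell (edgeR BH-adjusted p = 0.00412, 0.00372 and 0.00462). Hoxc10 was at least 195-fold lower in BAT than in IWAT, and Hoxa10 had 1 count in BAT and 644 in IWAT, a ratio of 668 (95% counting interval 119.9 to 26391). Against RWAT, edgeR called 4 genes. Zic1 rose by 4.51 ± 0.57, and Hoxa9, at -5.25 ± 0.67, Hoxa10 and Hoxc10 fell (edgeR BH-adjusted p = 0.0209, 0.0209, 0.0209 and 0.0209). In this pair Hoxc10 was at least 81.9-fold lower, and Hoxa10 had 1 count in BAT and 285 in RWAT, a ratio of 289 (95% counting interval 52.0 to 11434). The genes named for these 3 pairs were chosen after their values were seen. DESeq2 called 477, 321 and 45 genes against EWAT, IWAT and RWAT, and limma-voom 16, 0 and 0. At an unadjusted p below 0.05, edgeR had 1884, 2501 and 894.

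Left-out libraries moved the counts of these BAT pairs. Against EWAT the count was 3 without BAT 1, 247 without BAT 2, 9 without BAT 3, 13 without EWAT 1, 8 without EWAT 2, 4 without EWAT 3, 11 without IWAT 2, 46 without RWAT 1 and 46 without RWAT 2, and with the replicate number as a block it was 13. Against IWAT it was 3 without BAT 1, 82 without BAT 2, 11 without BAT 3 and 9 without EWAT 1. Against RWAT it was 1 without BAT 1 or EWAT 2, 28 without BAT 2, 2 without BAT 3, 13 without RWAT 2 and 0 without EWAT 1, EWAT 3, IWAT 2 or RWAT 3. Of Tbx15, Zic1, Krt8 and Krt18 against EWAT, calls ended for 2 without BAT 1, 2 without BAT 3, 1 without EWAT 2, 2 without EWAT 3, 1 without IWAT 1 and 1 without IWAT 2, with Krt8 in each and Krt18 where the number is 2 (edgeR BH-adjusted p 0.0529 to 0.130). Of the 4 genes named against IWAT, the call ended for 1 without BAT 1 (edgeR BH-adjusted p = 0.0887), and of the 4 against RWAT for 3 without BAT 1, 1 without BAT 2, 4 without BAT 3, 4 without EWAT 1, 3 without EWAT 2, 4 without EWAT 3, 4 without IWAT 2, 2 without RWAT 1 and 4 without RWAT 3 (edgeR BH-adjusted p 0.0501 to 0.339). Other alternatives ended 2 without both EWAT 1 and BAT 2, 2 with limma-voom and 2 with the replicate number as a block (BH-adjusted p 0.0541 to 0.200) against EWAT, 2 with the adipocyte covariate, 4 with limma-voom and 4 with only the groups compared (BH-adjusted p 0.0528 to 0.302) against IWAT and 4 without both RWAT 1 and RWAT 3, 3 without both EWAT 1 and BAT 2, 3 with the adipocyte covariate, 4 with limma-voom and 2 with only the groups compared (BH-adjusted p 0.0523 to 1.00) against RWAT. Between BAT and RWAT, where the libraries with the same number correlated by 0.182 to 0.429, the replicate number as a block left 3 genes called. Zic1 was then not called (log2 fold change 4.46, edgeR BH-adjusted p = 0.149, against 3.5e-09 to 0.546 over its 25 alternatives, those with DESeq2 and limma-voom included).

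Of the 7 comparisons, edgeR called the most genes between inguinal fat, a subcutaneous depot, and epididymal fat, a gonadal depot. Camera called the macrophage, cytokine, cell cycle and mesothelial lists higher in EWAT, and those of adipocyte lipid metabolism, fibroblast progenitors and posterior homeobox genes higher in IWAT. All of these list calls were lost with an estimated correlation (adjusted p = 0.364 to 0.421). In EWAT and IWAT osteopontin, Spp1, stood at 3742 ± 1394 and 54.9 ± 55.9 CPM. Tbx15 stood at 0.207 ± 0.0710 and 21.2 ± 3.45 CPM.

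Between IWAT and EWAT, edgeR called 2082 of 18942 genes at a BH-adjusted p below 0.05, 1037 higher and 1045 lower in IWAT. Of genes with separated libraries, the largest rises were those of the protocadherin Pcdh20 (7.59 ± 1.05), the steroid enzyme Akr1c18 (7.29 ± 1.21), the methyltransferase Inmt (6.74 ± 1.3), Tbx15 (6.65 ± 0.55) and the secreted Retnla (6.55 ± 1.26). Their edgeR BH-adjusted p were 0.00532, 0.0108, 0.0166, 0.00121 and 0.0167. The largest falls were those of Krt8 (-8.92 ± 1.14), the mesothelial transcription factor Wt1 (-8.14 ± 1.36), arginase Arg1 (-6.60 ± 1.09), Cemip, which acts on hyaluronan (-6.46 ± 1.77), and Spp1 (-6.09 ± 1.10). Their edgeR BH-adjusted p were 0.00349, 0.00980, 0.0114, 0.0424 and 0.0138. In counts, Krt8 had 2 in IWAT and 1245 in EWAT, a ratio of 577 (95% counting interval 159.8 to 4767). Wt1 (chromosome 2, 105126529 to 105173616) had 3 and 1032, a ratio of 319 (109 to 1547). EWAT 2 held all 5 counts of Akr1c18 in EWAT, and without it the fitted log2 fold change was 11.11, which is no bound. The calls that ended among these 10 genes numbered 2 without EWAT 1, 1 without EWAT 2, 3 without EWAT 3, 1 without IWAT 1 and 6 without IWAT 2 (edgeR BH-adjusted p 0.0515 to 0.126). By other alternatives the numbers were 1 without both EWAT 1 and BAT 2, 9 with the adipocyte covariate, 2 with limma-voom and 1 with the replicate number as a block (BH-adjusted p 0.0558 to 0.320). The count was 575 without EWAT 1, 263 without EWAT 3, 304 without IWAT 1, 55 without IWAT 2 and 1353 without RWAT 1, 1064 with the replicate number as a block and 3780 by DESeq2, and alternatives chosen after seeing the data gave 1071 without EWAT 1 and BAT 2, 1141 without RWAT 1 and RWAT 3, and 2, Tbx15 and Bcl2a1b, with the adipocyte score as a covariate.

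The macrophage, cytokine and cell cycle lists were called lower in IWAT than in EWAT by camera (adjusted p = 0.386 for each with an estimated correlation). Of the 20 macrophage genes tested, 1 rose and 13 fell over all genes, and 17 were lower and 1 higher adjusted over the list alone. The macrophage genes had a median log2 fold change of -1.86 (camera BH-adjusted p = 6.29e-08, adjusted p = 0.386 with an estimated correlation). The scavenger receptor Msr1 fell by a log2 fold change of 3.02 ± 0.41, lysozyme Lyz2 by 2.23 ± 0.42 and the chemokine receptor Cx3cr1 by 3.81 ± 0.72 (edgeR BH-adjusted p = 0.00832, 0.0157 and 0.0159). Of the 16 lipid-associated macrophage genes tested, 4 fell over all genes, and 11 were lower adjusted over the list alone. The lipid-associated macrophage genes had a median log2 fold change of -1.69 (camera BH-adjusted p = 1.02e-05, adjusted p = 0.386 with an estimated correlation). That median was -1.04 without EWAT 3. The members that fell included Spp1 and the tetraspanins Cd9 (-1.68 ± 0.34) and Cd63 (-0.93 ± 0.22, edgeR BH-adjusted p = 0.0189 and 0.0290). Of the 21 inflammatory cytokine genes tested, 5 fell over all genes, and 10 were lower adjusted over the list alone. The inflammatory cytokine genes had a median log2 fold change of -1.69 (camera BH-adjusted p = 7.43e-05, adjusted p = 0.386 with an estimated correlation). Tumour necrosis factor, Tnf, had a log2 fold change of -2.33 ± 0.53, the chemokine Ccl7 -2.02 ± 0.47 and Il6 -3.43 ± 0.84 (edgeR BH-adjusted p = 0.0254, 0.0268 and 0.0318). Of the 18 cell cycle genes tested, 4 fell over all genes, and 17 were lower adjusted over the list alone. The cell cycle genes had a median log2 fold change of -1.64 (camera BH-adjusted p = 6.29e-08, adjusted p = 0.386 with an estimated correlation). That median was -0.93 with the adipocyte covariate. The replication clamp Pcna had a log2 fold change of -1.57 ± 0.37 and thymidylate synthase, Tyms, -1.23 ± 0.31 (edgeR BH-adjusted p = 0.0280 and 0.0342). Calls among these 11 genes ended for 4 without EWAT 1, 1 without EWAT 2, 7 without EWAT 3, 8 without IWAT 1, 11 without IWAT 2 and 1 without IWAT 3 (edgeR BH-adjusted p 0.0511 to 0.104). Other alternatives ended 3 without both RWAT 1 and RWAT 3, 4 without both EWAT 1 and BAT 2, 11 with the adipocyte covariate, 1 with limma-voom, 2 with only the groups compared and 2 with the replicate number as a block (BH-adjusted p 0.0509 to 0.417).

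The adipocyte lipid lists were called higher in IWAT by camera (adjusted p = 0.386 to 0.421 with an estimated correlation), and the adipocyte score moved with them. The mean log2 CPM of the pan-adipocyte genes was 10.07, 9.43 and 9.69 in IWAT 1 to 3 and 5.52, 8.54 and 7.85 in EWAT 1 to 3. Of the 17 pan-adipocyte genes tested, 1 rose over all genes, and 6 were higher adjusted over the list alone. The pan-adipocyte genes had a median log2 fold change of 2.18 (camera BH-adjusted p = 1.89e-06, adjusted p = 0.421 with an estimated correlation). The adipocyte transcription factor Cebpa rose by 1.46 ± 0.39 (edgeR BH-adjusted p = 0.0388). Of the 15 white adipocyte genes tested, 2 rose over all genes, and 6 were higher adjusted over the list alone. The white adipocyte genes had a median log2 fold change of 1.5 (camera BH-adjusted p = 7.43e-05, adjusted p = 0.386 with an estimated correlation). That median was -0.032 with the adipocyte covariate. The call ended with the adipocyte covariate (camera BH-adjusted p = 0.464), against 3.47e-06 to 0.464 over its 24 alternatives with the preset correlation. With the covariate camera's direction stayed up while the median turned negative. Mest, a marker of fat expansion, rose by 1.56 ± 0.36 (edgeR BH-adjusted p = 0.0273). Of the 16 lipolysis genes tested, 2 rose over all genes, and 16 were higher adjusted over the list alone. The lipolysis genes had a median log2 fold change of 1.94 (camera BH-adjusted p = 1.8e-07, adjusted p = 0.386 with an estimated correlation). That median was 0.41 with the adipocyte covariate. The members that rose were the natriuretic peptide receptor Npr1 (2.05 ± 0.36) and the phosphodiesterase Pde3b (1.65 ± 0.45, edgeR BH-adjusted p = 0.0132 and 0.0417). Of the 17 fatty acid synthesis genes tested, 5 rose over all genes, and 10 were higher adjusted over the list alone. The fatty acid synthesis genes had a median log2 fold change of 1.79 (camera BH-adjusted p = 5.62e-04, adjusted p = 0.386 with an estimated correlation). That median was 1.00 with the adipocyte covariate. The lipogenic regulator Srebf1 rose by 1.76 ± 0.35, the synthetase Aacs by 1.79 ± 0.36 and the carboxylase Acacb by 3.15 ± 0.71 (edgeR BH-adjusted p = 0.0187, 0.0187 and 0.0251). Of the 15 triglyceride synthesis genes tested, 4 rose and 1 fell over all genes, and 10 were higher and 1 lower adjusted over the list alone. The triglyceride synthesis genes had a median log2 fold change of 1.98 (camera BH-adjusted p = 4.13e-04, adjusted p = 0.386 with an estimated correlation). That median was 1.27 without IWAT 1 and 0.21 with the adipocyte covariate. The call ended with the adipocyte covariate (camera BH-adjusted p = 0.191), against 3.96e-05 to 0.191 over its 24 alternatives with the preset correlation. The acyltransferase Agpat9 rose by 2.11 ± 0.57, while the phosphatase Lpin2, at -0.95 ± 0.19, fell (edgeR BH-adjusted p = 0.0406 and 0.0189).

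The fatty acid oxidation and thermogenic lists were also called higher in IWAT by camera, with 3 of 20 and 2 of 23 members rising (adjusted p = 0.551 to 0.636 with an estimated correlation). Of the 20 fatty acid oxidation genes tested, 3 rose over all genes, and 10 were higher adjusted over the list alone. The fatty acid oxidation genes had a median log2 fold change of 1.36 (camera BH-adjusted p = 8.08e-05, adjusted p = 0.551 with an estimated correlation). That median was 0.24 with the adipocyte covariate. The call ended with the adipocyte covariate (camera BH-adjusted p = 0.126), against 1.78e-06 to 0.126 over its 24 alternatives with the preset correlation. The peroxisomal enzyme Ehhadh rose by 2.14 ± 0.46 (edgeR BH-adjusted p = 0.0226). Of the 23 thermogenic genes tested, 2 rose over all genes, and 2 were higher adjusted over the list alone. The thermogenic genes had a median log2 fold change of 1.52 (camera BH-adjusted p = 0.00499, adjusted p = 0.636 with an estimated correlation). That median was 0.57 with the adipocyte covariate. The call ended with the adipocyte covariate (camera BH-adjusted p = 0.0691), against 3.21e-04 to 0.0691 over its 24 alternatives with the preset correlation. The regulators of brown and beige fat Prdm16 and Ebf2 rose by 2.44 ± 0.50 and 1.81 ± 0.41 (edgeR BH-adjusted p = 0.0189 and 0.0261). The calls that ended among these 12 genes numbered 2 without BAT 1, EWAT 2 or IWAT 3, 8 without EWAT 1, 12 without EWAT 3 or IWAT 2, 9 without IWAT 1, 3 without RWAT 1 and 1 without RWAT 3 (edgeR BH-adjusted p 0.0508 to 0.131). By other alternatives the numbers were 4 without both RWAT 1 and RWAT 3, 5 without both EWAT 1 and BAT 2, 12 with the adipocyte covariate, 1 with only the groups compared, 2 with the replicate number as a block and 1 with the length offset (BH-adjusted p 0.0509 to 0.732). The pan-adipocyte list was not tested with the covariate, its own mean, which was chosen after seeing the data and followed depot (r = 0.793). The list shares 4 genes with the lipolysis list, 1 with the triglyceride synthesis list, 1 with the adrenergic receptor list and 0 with the white adipocyte, oxidation and thermogenic lists.

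Camera called the progenitor and posterior homeobox lists higher and the mesothelial list lower in IWAT (adjusted p = 0.364 to 0.386 with an estimated correlation). Of the 20 progenitor and fibroblast genes tested, 12 rose over all genes, and 12 were higher adjusted over the list alone. The progenitor and fibroblast genes had a median log2 fold change of 1.45 (camera BH-adjusted p = 7.43e-05, adjusted p = 0.386 with an estimated correlation). Pi16 and Dpp4, markers of interstitial progenitors, rose by 5.96 ± 0.94 and 3.63 ± 0.60, and the matrix protein decorin, Dcn, by 2.18 ± 0.43 (edgeR BH-adjusted p = 0.0108, 0.0114 and 0.0177). Ly6a, one of a family of similar genes whose count is uncertain, rose by 1.98 ± 0.36 (edgeR BH-adjusted p = 0.0140). Of the 17 mesothelial genes tested, 10 fell over all genes, and 12 were lower and 1 higher adjusted over the list alone. The mesothelial genes had a median log2 fold change of -2.70 (camera BH-adjusted p = 1.01e-06, adjusted p = 0.386 with an estimated correlation). That median was -4.10 without IWAT 1. Krt18 had a log2 fold change of -5.46 ± 0.90 and Nkain4 -5.08 ± 1.04 (edgeR BH-adjusted p = 0.00901 and 0.0156). Nkain4 had 3 counts in IWAT and 121 in EWAT, a ratio of 37.4 (95% counting interval 12.8 to 181). Of the 6 posterior homeobox genes tested, 3 rose over all genes, and 5 were higher adjusted over the list alone. The posterior homeobox genes had a median log2 fold change of 2.86 (camera BH-adjusted p = 7.44e-05, adjusted p = 0.364 with an estimated correlation). That median was 1.45 with no filter. Hoxc10 rose by 5.43 ± 0.59, Hoxa10 by 4.85 ± 0.66 and Hoxa9 by 3.93 ± 0.55 (edgeR BH-adjusted p = 0.00532, 0.00545 and 0.00705). Of the depot developmental genes, 7 of 19 rose and 3 fell over all genes, and 9 and 6 did adjusted over the list alone. The set was not called (camera BH-adjusted p = 0.0742). It was called higher with the 1 CPM filter, length offset and adipocyte covariate (camera BH-adjusted p = 0.0272, 0.0448 and 5.48e-04, up to 0.334 over its 24 alternatives). Its median log2 fold change was 1.12, also with its member at 0 counts set to its bound. Gata5, a zinc finger factor of visceral mesoderm, had a log2 fold change of -4.54 ± 0.84 and fell (edgeR BH-adjusted p = 0.0126). Calls among these 10 genes ended for 1 without EWAT 1, 2 without EWAT 3, 2 without IWAT 1 and 7 without IWAT 2 (edgeR BH-adjusted p 0.0508 to 0.0690). Other alternatives ended 10 with the adipocyte covariate (BH-adjusted p 0.0689 to 0.230).

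Among the lists tied to nerves and their signals, camera called those of adrenergic receptors and Schwann cells higher in IWAT (adjusted p = 0.386 for each with an estimated correlation). Of the 7 adrenergic receptor genes tested, 2 rose over all genes, and 3 were higher adjusted over the list alone. The adrenergic receptor genes had a median log2 fold change of 1.80 (camera BH-adjusted p = 0.00127, adjusted p = 0.386 with an estimated correlation). That median was 0.87 with the adipocyte covariate. The members that rose were the alpha receptors Adra1d (2.33 ± 0.38) and Adra1b (4.30 ± 1.06, edgeR BH-adjusted p = 0.0109 and 0.0309). Of the 13 Schwann cell genes tested, 3 rose over all genes, and 6 were higher and 1 lower adjusted over the list alone. The Schwann cell genes had a median log2 fold change of 1.45 (camera BH-adjusted p = 0.00499, adjusted p = 0.386 with an estimated correlation). That median was 0.95 with the adipocyte covariate and 2.30 without both RWAT 1 and RWAT 3. The glial cadherin Cdh19 rose by 6.33 ± 1.2 and the glial transcription factor Sox10 by 4.29 ± 0.81 (edgeR BH-adjusted p = 0.0132 and 0.0132). The sympathetic neuron list was not called (median log2 fold change 0.64, camera BH-adjusted p = 0.851, adjusted p = 0.944 with an estimated correlation). Its member Gap43, a growth cone protein, rose by 4.04 ± 0.90 (edgeR BH-adjusted p = 0.0235). The calls that ended among these 5 genes numbered 3 without EWAT 1, 1 without EWAT 2, 4 without EWAT 3, 1 without IWAT 1 and 5 without IWAT 2 (edgeR BH-adjusted p 0.0505 to 0.0932). By other alternatives the numbers were 1 without both EWAT 1 and BAT 2, 5 with the adipocyte covariate and 1 with limma-voom (BH-adjusted p 0.0656 to 0.693).

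**Figure D2:**
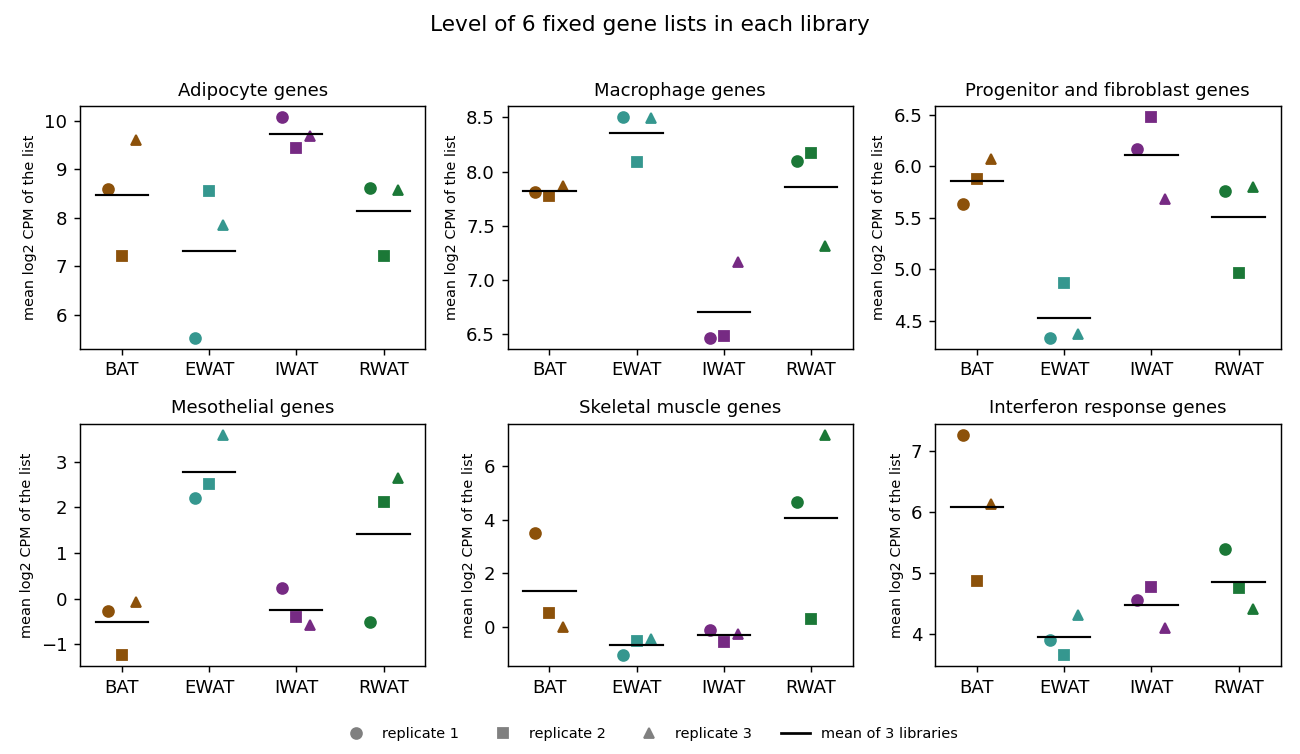
Mean log2 CPM of 6 gene lists in each of the 12 libraries, with a marker shape for each replicate number and a bar for the mean of the 3 libraries of a depot. The adipocyte score spans 5.52 in EWAT 1 to 10.07 in IWAT 1, and skeletal muscle genes are highest in RWAT 3 (7.17) and RWAT 1 (4.66).

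Retroperitoneal fat was compared with epididymal fat, the gonadal depot. Tbx15 stood at 11.8 ± 7.50 CPM in RWAT and 0.207 ± 0.0710 CPM in EWAT and was higher in 3 of 3 RWAT libraries than in any EWAT library. Camera called the skeletal muscle, progenitor, lymphatic and posterior homeobox lists higher in RWAT and the mesothelial list lower. All of these calls were lost with an estimated correlation (adjusted p = 0.155 to 0.550). The muscle transcripts were unevenly spread: creatine kinase, Ckm, stood at 60.4, 0.182 and 338 CPM in RWAT 1 to 3.

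Between RWAT and EWAT, edgeR called 1 gene, Tbx15 (chromosome 3, 99240381 to 99354259), which rose by a log2 fold change of 5.8 ± 0.54 (edgeR BH-adjusted p = 0.00427). The count was 0 without EWAT 1 or EWAT 2, 2 without EWAT 3, IWAT 1, IWAT 2 or RWAT 1, 4 without IWAT 3, 79 without RWAT 2 and 3 without RWAT 3. The BH-adjusted p of Tbx15 by edgeR was 0.0923 without EWAT 1 and 0.0603 without EWAT 2, and 7.42e-18 to 0.397 over its 25 alternatives, those with DESeq2 and limma-voom included. It was 0.397 by limma-voom, 0.0661 with only the groups compared and 0.169 without both EWAT 1 and BAT 2. DESeq2 called 130 genes and limma-voom 0, and 912 had an unadjusted edgeR p below 0.05, which is not above the 947 expected by chance. Camera called 23 of 48 lists, against 11 without RWAT 1. Of the 18 skeletal muscle genes tested, edgeR called 0 over all genes, and 17 were higher adjusted over the list alone. DESeq2 called 14 and limma-voom 0, and 17 had an unadjusted edgeR p below 0.05. The skeletal muscle genes had a median log2 fold change of 7.14 (camera BH-adjusted p = 2.83e-21, adjusted p = 0.272 with an estimated correlation). That median was 4.58 without RWAT 3 and 1.26 without both RWAT 1 and RWAT 3. Ckm had a log2 fold change of 9.86 ± 1.99 and Actn3, an actinin of fast fibres, 6.83 ± 1.40 (edgeR BH-adjusted p = 0.225 and 0.234). Of the 20 progenitor and fibroblast genes tested, edgeR called 0 over all genes, and 5 were higher adjusted over the list alone. By limma-voom the number was 0, by DESeq2 it was 3, and 10 had an unadjusted edgeR p below 0.05. The progenitor and fibroblast genes had a median log2 fold change of 0.91 (camera BH-adjusted p = 6.46e-08, adjusted p = 0.155 with an estimated correlation). That median was 0.38 without both RWAT 1 and RWAT 3. Pi16 had a log2 fold change of 3.98 ± 0.86 and Dpp4 2.16 ± 0.57 (edgeR BH-adjusted p = 0.253 and 0.409). Of the 6 posterior homeobox genes tested, edgeR called 0 over all genes, and 3 were higher adjusted over the list alone. An unadjusted edgeR p below 0.05 was reached by 3, and DESeq2 called 3 and limma-voom 0. The posterior homeobox genes had a median log2 fold change of 1.75 (camera BH-adjusted p = 7.61e-06, adjusted p = 0.155 with an estimated correlation). That median was 0.15 with no filter and 0.084 without both RWAT 1 and RWAT 3. Hoxc10 had a log2 fold change of 4.13 ± 0.59, with an edgeR BH-adjusted p of 0.192.

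Camera also called lists of other cell types between RWAT and EWAT (adjusted p = 0.155 to 0.711 with an estimated correlation). Of the 19 interferon response genes tested, edgeR called 0 over all genes, and 0 passed adjusted over the list alone. The number was 3 at an unadjusted edgeR p below 0.05, 0 by DESeq2 and 0 by limma-voom. The interferon response genes had a median log2 fold change of 1.02 (camera BH-adjusted p = 1.44e-07, adjusted p = 0.602 with an estimated correlation). That median was 0.60 without RWAT 1. Oas2 had a log2 fold change of 1.21 ± 0.33 (edgeR BH-adjusted p = 0.496). Of the 8 lymphatic endothelial genes tested, edgeR called 0 over all genes, and 2 were higher adjusted over the list alone. At an unadjusted p below 0.05 edgeR had 3, and DESeq2 called 0 and limma-voom 0. The lymphatic endothelial genes had a median log2 fold change of 1.71 (camera BH-adjusted p = 0.00382, adjusted p = 0.155 with an estimated correlation). That median was 1.09 without RWAT 1 and 0.66 without both RWAT 1 and RWAT 3. Lyve1, a hyaluronan receptor of lymphatic vessels, had a log2 fold change of 2.08 ± 0.65 (edgeR BH-adjusted p = 0.675). Of the 17 mesothelial genes tested, edgeR called 0 over all genes, and 3 were lower adjusted over the list alone. DESeq2 called 0 and limma-voom 0, and 3 had an unadjusted edgeR p below 0.05. The mesothelial genes had a median log2 fold change of -0.96 (camera BH-adjusted p = 1.24e-06, adjusted p = 0.550 with an estimated correlation). That median was -0.12 without EWAT 3 and -1.71 without RWAT 3. Krt18 had a log2 fold change of -2.92 ± 0.73 (edgeR BH-adjusted p = 0.311). Wt1 stood at 0, 8.05 and 7.20 CPM in RWAT 1 to 3. Of the 20 macrophage genes tested, edgeR called 0 over all genes, and 0 passed adjusted over the list alone. By limma-voom the number was 0, by DESeq2 it was 1, and 2 had an unadjusted edgeR p below 0.05. The macrophage genes had a median log2 fold change of -0.47 (camera BH-adjusted p = 1.37e-04, adjusted p = 0.550 with an estimated correlation). That median was -0.23 without EWAT 3, -0.19 without RWAT 3 and -0.28 without both RWAT 1 and RWAT 3. The call ended without RWAT 3 (camera BH-adjusted p = 0.202) and without both RWAT 1 and RWAT 3 (camera BH-adjusted p = 0.279), against 1.15e-05 to 0.279 over its 24 alternatives with the preset correlation. Cx3cr1 had a log2 fold change of -1.71 ± 0.66, and the mannose receptor Mrc1 went the other way at 0.93 ± 0.32 (edgeR BH-adjusted p = 0.838 and 0.717). Of the 17 pan-adipocyte genes tested, edgeR called 0 over all genes, and 0 passed adjusted over the list alone. An unadjusted edgeR p below 0.05 was reached by 0, and DESeq2 called 0 and limma-voom 0. The pan-adipocyte genes had a median log2 fold change of 0.44 (camera BH-adjusted p = 0.00513, adjusted p = 0.711 with an estimated correlation). That median was -0.019 without EWAT 1, 1.12 without EWAT 2, 0.23 without RWAT 1, 0.78 without RWAT 2, 0.28 without RWAT 3, 0.76 with limma-voom, -0.034 without both EWAT 1 and BAT 2 and -0.66 without both RWAT 1 and RWAT 3. The call ended without EWAT 1 (camera BH-adjusted p = 0.664), without RWAT 1 (camera BH-adjusted p = 0.154), without both EWAT 1 and BAT 2 (camera BH-adjusted p = 0.655) and without both RWAT 1 and RWAT 3 (camera BH-adjusted p = 0.710), against 9.82e-05 to 0.710 over its 23 alternatives with the preset correlation.

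RWAT was last compared with inguinal fat. Camera called the macrophage, cytokine, cell cycle, mesothelial and skeletal muscle lists higher in RWAT and the lipolysis, pan-adipocyte, fatty acid synthesis and triglyceride synthesis lists lower. None of these list calls held with an estimated correlation (adjusted p = 0.452 to 0.520). Spp1 stood at 1277 ± 766 CPM in RWAT and 54.9 ± 55.9 CPM in IWAT, and the lipogenic regulator Srebf1 at 100.4 ± 36.8 and 289 ± 94.4 CPM.

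Between RWAT and IWAT, edgeR called 0 of 18942 genes at a BH-adjusted p below 0.05, while 3909 had an unadjusted p below 0.05, DESeq2 called 1150 and limma-voom 0. The edgeR count was 3 without BAT 3, 4 without RWAT 1, 61 without RWAT 2 and 31 without RWAT 3. Of the 20 macrophage genes tested, edgeR called 0 over all genes, and 13 were higher adjusted over the list alone. The number was 13 at an unadjusted edgeR p below 0.05, 6 by DESeq2 and 0 by limma-voom. The macrophage genes had a median log2 fold change of 1.40 (camera BH-adjusted p = 2.1e-07, adjusted p = 0.452 with an estimated correlation). Msr1 had a log2 fold change of 2.42 ± 0.40 and Lyz2 1.36 ± 0.41 (edgeR BH-adjusted p = 0.103 and 0.138). Of the 16 lipid-associated macrophage genes tested, edgeR called 0 over all genes, and 3 were higher and 1 lower adjusted over the list alone. At an unadjusted p below 0.05 edgeR had 7, and DESeq2 called 3 and limma-voom 0. The lipid-associated macrophage genes had a median log2 fold change of 1.18 (camera BH-adjusted p = 6.25e-05, adjusted p = 0.452 with an estimated correlation). That median was 1.87 without IWAT 3. Its member Spp1 had a log2 fold change of 4.54 ± 1.02 (edgeR BH-adjusted p = 0.104). Of the 21 inflammatory cytokine genes tested, edgeR called 0 over all genes, and 10 were higher adjusted over the list alone. DESeq2 called 9 and limma-voom 0, and 12 had an unadjusted edgeR p below 0.05. The inflammatory cytokine genes had a median log2 fold change of 1.83 (camera BH-adjusted p = 4.11e-05, adjusted p = 0.452 with an estimated correlation). Ccl7 had a log2 fold change of 2.58 ± 0.48 (edgeR BH-adjusted p = 0.103). Of the 18 cell cycle genes tested, edgeR called 0 over all genes, and 12 were higher adjusted over the list alone. By limma-voom the number was 0, by DESeq2 it was 2, and 15 had an unadjusted edgeR p below 0.05. The cell cycle genes had a median log2 fold change of 1.38 (camera BH-adjusted p = 1.12e-08, adjusted p = 0.452 with an estimated correlation). That median was 0.90 with the adipocyte covariate. Pcna had a log2 fold change of 1.32 ± 0.37 (edgeR BH-adjusted p = 0.133). Of the 17 mesothelial genes tested, edgeR called 0 over all genes, and 9 were higher adjusted over the list alone. An unadjusted edgeR p below 0.05 was reached by 9, and DESeq2 called 6 and limma-voom 0. The mesothelial genes had a median log2 fold change of 2.54 (camera BH-adjusted p = 2.65e-04, adjusted p = 0.520 with an estimated correlation). That median was 1.40 without RWAT 3 and 1.44 with only the groups compared. The call ended with only the groups compared (camera BH-adjusted p = 0.0753), against 5.94e-11 to 0.0753 over its 24 alternatives with the preset correlation. Wt1 had 3 counts in IWAT and 272 in RWAT, a ratio of 88.8 (95% counting interval 30.4 to 430.4, edgeR BH-adjusted p = 0.103).

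The skeletal muscle list was called higher in RWAT than in IWAT by camera and the lipid lists lower (adjusted p = 0.452 to 0.520 with an estimated correlation). Of the 18 skeletal muscle genes tested, edgeR called 0 over all genes, and 17 were higher adjusted over the list alone. The number was 17 at an unadjusted edgeR p below 0.05, 14 by DESeq2 and 0 by limma-voom. The skeletal muscle genes had a median log2 fold change of 6.82 (camera BH-adjusted p = 1.12e-08, adjusted p = 0.452 with an estimated correlation). That median was 0.95 without both RWAT 1 and RWAT 3. The call ended without both RWAT 1 and RWAT 3 (camera BH-adjusted p = 0.0765), against 3.28e-25 to 0.0765 over its 24 alternatives with the preset correlation. Ckm had 3 counts in IWAT and 5712 in RWAT, a ratio of 1864 (95% counting interval 638 to 9038, edgeR BH-adjusted p = 0.103). Ckm stood at 60.4, 0.182 and 338 CPM in RWAT 1 to 3. Of the 16 lipolysis genes tested, edgeR called 0 over all genes, and 0 passed adjusted over the list alone. At an unadjusted p below 0.05 edgeR had 11, and DESeq2 called 3 and limma-voom 0. The lipolysis genes had a median log2 fold change of -1.35 (camera BH-adjusted p = 2.95e-06, adjusted p = 0.452 with an estimated correlation). That median was -0.38 with the adipocyte covariate and -2.29 without both RWAT 1 and RWAT 3. Npr1 had a log2 fold change of -1.13 ± 0.35 (edgeR BH-adjusted p = 0.144). Of the 17 pan-adipocyte genes tested, edgeR called 0 over all genes, and 1 was lower adjusted over the list alone. DESeq2 called 1 and limma-voom 0, and 7 had an unadjusted edgeR p below 0.05. The pan-adipocyte genes had a median log2 fold change of -1.63 (camera BH-adjusted p = 2.69e-05, adjusted p = 0.520 with an estimated correlation). That median was -2.75 without both RWAT 1 and RWAT 3. Cebpa had a log2 fold change of -1.51 ± 0.39 (edgeR BH-adjusted p = 0.121). Of the 17 fatty acid synthesis genes tested, edgeR called 0 over all genes, and 7 were lower adjusted over the list alone. By limma-voom the number was 0, by DESeq2 it was 6, and 8 had an unadjusted edgeR p below 0.05. The fatty acid synthesis genes had a median log2 fold change of -1.71 (camera BH-adjusted p = 6.25e-05, adjusted p = 0.452 with an estimated correlation). That median was -1.09 without IWAT 1 and -1.07 with the adipocyte covariate. Aacs had a log2 fold change of -1.71 ± 0.36 and Srebf1 -1.52 ± 0.35 (edgeR BH-adjusted p = 0.103 and 0.107). Of the 15 triglyceride synthesis genes tested, edgeR called 0 over all genes, and 11 were lower and 1 higher adjusted over the list alone. An unadjusted edgeR p below 0.05 was reached by 11, and DESeq2 called 6 and limma-voom 0. The triglyceride synthesis genes had a median log2 fold change of -1.69 (camera BH-adjusted p = 6.33e-05, adjusted p = 0.452 with an estimated correlation). That median was -0.43 with the adipocyte covariate. The acyltransferase Gpat4 had a log2 fold change of -0.83 ± 0.18 (edgeR BH-adjusted p = 0.103).

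The genes of fat hormones and of noradrenaline signalling chosen beforehand varied widely between libraries of most depots. Adipoq and Adrb3 varied less in IWAT. Leptin, Lep, stood at 406 ± 462 in BAT, 369 ± 389.5 in EWAT, 1041 ± 497 in IWAT and 499 ± 267 in RWAT (CPM). Adiponectin, Adipoq, stood at 1011 ± 1114 in BAT, 448 ± 502 in EWAT, 2066 ± 312 in IWAT and 667 ± 378 in RWAT. The beta receptor Adrb3 stood at 101 ± 112 in BAT, 24.8 ± 32.3 in EWAT, 133 ± 30.0 in IWAT and 43.4 ± 35.7 in RWAT. Ucp1 stood at 497 ± 859 in BAT, 0.783 ± 1.23 in EWAT, 4.88 ± 3.58 in IWAT and 0.764 ± 0.640 in RWAT. In the 7 comparisons edgeR and limma-voom each called Lep, Adipoq, Adrb3 and Ucp1 0 times, and DESeq2 called the first 3 of them 0 times and gave no adjusted p for Ucp1. Ucp1 had an unadjusted edgeR p below 0.05 in 4 comparisons and the others in 0. Tyrosine hydroxylase, Th, the first enzyme of noradrenaline synthesis, had 1 count in EWAT 2 and 0 in each of the other 11 libraries, where 3 counts equal up to 0.227 CPM, so its level was not detectable at this depth.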

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

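The adipocyte covariate and the sets of 2 left-out libraries were chosen after seeing the data, and the other alternatives were planned. A result was counted as reversed only where its sign (camera's direction for lists) changed and it passed the threshold before or after. No alternative reversed any of the 301 results of named genes in this sense. Sign changes of genes called in neither fit were counted among the 6719 values that kept their side of the threshold. Of the other values, 576 fell short of it and 198 passed it. For 67 results of lists these numbers were 1575, 75 and 12, and 9 reversed. Gene counts are given below in the order BAT against the white mean, EWAT, IWAT and RWAT, then IWAT against EWAT, RWAT against EWAT and RWAT against IWAT. With the usual settings they were 10, 27, 5, 4, 2082, 1 and 0. DESeq2 gave 180, 477, 321, 45, 3780, 130 and 1150 and limma-voom 4, 16, 0, 0, 1886, 0 and 0. A fit of only the groups compared, with fewer samples, gave 4, 21, 0, 2, 1446, 0 and 2, and no filter, with more genes tested, 21, 63, 6, 4, 1631, 2 and 0. The adipocyte covariate gave 5, 24, 2, 1, 2, 1 and 0. Without EWAT 1 and BAT 2 they were 208, 5, 59, 17, 1071, 0 and 1, and without RWAT 1 and RWAT 3 4, 36, 4, 0, 1141, 1 and 3, where RWAT 2 alone is assumed to vary like the other groups. Between RWAT and EWAT, RLE factors and the length offset each gave 2. The replicate number as a block gave 7, 13, 4, 3, 1064, 1 and 0, and Zic1 lost its call between BAT and RWAT. Correlations of libraries with the same number averaged -0.0124 over 18 pairs (-0.359 to 0.429), with 8 over 0.1, among them all 3 of BAT with RWAT (0.182 to 0.429) but not all 3 of any other pair of depots. Leaving out 1 library gave 1 to 251, 3 to 247, 3 to 82, 0 to 28, 55 to 2769, 0 to 79 and 0 to 61. Lists called numbered 15, 25, 23 and 23 and 16 to 21, 23 to 28, 11 to 26 and 19 to 28 with 1 library left out, and 1, 0, 0 and 0 with an estimated correlation. The share of mitochondrial protein genes differed by -0.254 to 1.01 points. Where these counts moved, the cause was not tested, apart from fewer samples or another number of genes.

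Reversed list medians against white fat were, without BAT 1, -0.065 for thermogenic, -0.068 for oxidation, -0.16 for tricarboxylic acid cycle and -1.08 for muscle genes. Without BAT 2 it was -0.057 for fibrillar matrix genes. For pan-adipocyte genes camera's direction turned from down to up without BAT 2. The list, not called before, was then called (median 0.65, from 0.24, camera BH-adjusted p = 0.0218). Without BAT 3 it was called lower (median -0.47, camera BH-adjusted p = 0.0129). With each library left out these 6 medians spanned -0.065 to 2.01, -0.068 to 0.96, -0.16 to 0.87, -1.08 to 1.70, -0.057 to 0.65 and -0.47 to 0.65. Between RWAT and EWAT the pan-adipocyte median was -0.034 without EWAT 1 and BAT 2 and -0.66 without RWAT 1 and RWAT 3, and -0.019 to 1.12 with each library left out, the lowest without EWAT 1. Between IWAT and EWAT the covariate, the pan-adipocyte mean, took the white adipocyte median to -0.032, while camera's direction stayed up. The cause was not tested. Depth limits low genes: 3 counts are up to 0.227 CPM, reached in RWAT 3.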

Other observations

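The tests of explanations and the readings of the splits were written after the results were seen, while the splits and the gene lists were planned. Camera called the hormone receptor and clock lists higher in IWAT than in EWAT (adjusted p = 0.386 for each with an estimated correlation). Of the 23 peptide and hormone receptor genes tested, 9 rose over all genes, and 13 were higher and 2 lower adjusted over the list alone. The peptide and hormone receptor genes had a median log2 fold change of 1.55 (camera BH-adjusted p = 5.51e-05, adjusted p = 0.386 with an estimated correlation). That median was 0.45 with the adipocyte covariate. The receptor partner Ramp2 rose by 1.38 ± 0.20, the growth factor receptor Fgfr1 by 1.55 ± 0.31, the thyroid hormone receptor Thra by 1.86 ± 0.39 and the insulin receptor Insr by 1.62 ± 0.34 (edgeR BH-adjusted p = 0.00901, 0.0182, 0.0206 and 0.0218). Of the 18 circadian clock genes tested, 5 rose over all genes, and 11 were higher and 1 lower adjusted over the list alone. The circadian clock genes had a median log2 fold change of 1.03 (camera BH-adjusted p = 0.00169, adjusted p = 0.386 with an estimated correlation). That median was 0.45 with the adipocyte covariate. The clock repressors Nr1d1, Cry2, Per1 and Per3 rose by 2.02 ± 0.39, 1.93 ± 0.45, 0.96 ± 0.23 and 1.61 ± 0.44 (edgeR BH-adjusted p = 0.0159, 0.0273, 0.0293 and 0.0419). Calls among these 8 genes ended for 6 without EWAT 1, 7 without EWAT 3, IWAT 1 or IWAT 2 and 1 without BAT 1, IWAT 3 or RWAT 1 (edgeR BH-adjusted p 0.0505 to 0.135). Other alternatives ended 2 without both RWAT 1 and RWAT 3, 1 without both EWAT 1 and BAT 2, 8 with the adipocyte covariate, 1 with the replicate number as a block and 1 with the length offset (BH-adjusted p 0.0518 to 0.578).

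The vessel and cytokine lists were called higher in BAT than in white fat by camera (adjusted p = 0.209 to 0.442 with an estimated correlation), but the scores of BAT and white libraries overlapped. The cytokine score was 3.59 to 4.51 in BAT, 3.56 to 4.34 in EWAT, 3.12 to 4.29 in RWAT and 1.74 to 2.69 in IWAT, and the endothelial score 5.62 to 5.91, 4.42 to 5.68, 4.77 to 5.30 and 4.71 to 6.07. Of the 17 endothelial genes tested, edgeR called 0 over all genes, and 0 passed adjusted over the list alone. At an unadjusted p below 0.05 edgeR had 3, and DESeq2 called 0 and limma-voom 0. The endothelial genes had a median log2 fold change of 0.56 (camera BH-adjusted p = 2.8e-08, adjusted p = 0.442 with an estimated correlation). The vessel genes Eng and Mmrn2 had log2 fold changes of 0.72 ± 0.26 and 0.81 ± 0.31 (edgeR BH-adjusted p = 0.660 and 0.785). Of the 21 inflammatory cytokine genes tested, edgeR called 0 over all genes, and 6 were higher adjusted over the list alone. DESeq2 called 3 and limma-voom 0, and 9 had an unadjusted edgeR p below 0.05. The inflammatory cytokine genes had a median log2 fold change of 0.69 (camera BH-adjusted p = 3.6e-07, adjusted p = 0.209 with an estimated correlation). The interferon-induced chemokines Cxcl10 and Cxcl9 had log2 fold changes of 3.10 ± 0.58 and 2.70 ± 0.51 (edgeR BH-adjusted p = 0.104 and 0.112). Cxcl10 stood at 79.7, 5.32 and 88.6 CPM in BAT 1 to 3.

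Ucp1 and Cidea were far lower in BAT 2 and BAT 3 than in BAT 1. Libraries of a white depot under a BAT label are argued against, since the lower Zic1 level of BAT 2 and BAT 3 was 15.7 times that of the highest white library. Fewer adipocytes alone are argued against too, since Ucp1 per Adipoq in BAT 2 was 0.0577% of that in BAT 1, and in BAT 3 0.0293%. White fat like that of EWAT, IWAT or RWAT, sampled with the brown depot, is argued against as the whole cause. Zic1 and Lhx8 in BAT 2 and BAT 3 were at least 87.9% of BAT 1, against at most 0.114% for Ucp1. White fat from the site of BAT itself stays open, since no such library shows its level of Zic1 and Lhx8. Nerve fibres left in BAT 1 stay open, since Th had 0 counts there, with nerve cell bodies outside the fat, while the Schwann cell score was 2.19 against 0.24 and 0.81 in BAT 2 and BAT 3 and the sympathetic neuron score 0.63 against 1.36 and 0.90, and a loss of the brown programme after denervation or on the diet may also account for it but was not tested, as no innervated library was part of the series as analysed here.

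The RWAT libraries were unlike one another in muscle and mesothelial transcripts. Skeletal muscle taken along with the depot is a candidate source in RWAT 1 and RWAT 3: 16 of 18 muscle genes were above all EWAT and IWAT libraries in both, against 6 in RWAT 2. The most abundant of them in RWAT 3, titin (Ttn) and the fast myosin Myh4, stood at 2380 and 889 CPM there and 336 and 198 CPM in RWAT 1. Whether RWAT 1, which had 0 counts of Wt1, is an IWAT library under another label cannot be told apart from a real RWAT library. On an axis from the EWAT mean at 0 to the IWAT mean at 1 it lay at 0.485, against 0.750 to 1.17 for IWAT libraries held out in turn and 0.509 for RWAT 3.

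Adipocyte and macrophage genes lay apart between IWAT and EWAT. A higher adipocyte share of the RNA in IWAT and nothing else is argued against, since 12 of 20 progenitor genes rose while 13 of 20 macrophage genes fell and 1 rose (both camera calls were lost, adjusted p = 0.386 for each with an estimated correlation), and the lowest IWAT library exceeded the highest EWAT library by 1.74 in the difference of these log2 scores. A varying adipocyte share may still be part of it: the first principal component without the pan-adipocyte, white adipocyte and macrophage genes, with 38.5% of the variance, followed the adipocyte score (Pearson r = 0.937, p = 1e-05, the smallest the permutations can give, adjusted p = 4e-05 over 4 relations; Spearman rho = 0.930, permutation p = 9e-05, BH-adjusted p = 3.6e-04) and kept r = 0.938 without EWAT 1 and IWAT 1. It followed the macrophage score inversely as well (Pearson r = -0.864, permutation p = 1.7e-04, adjusted p = 3.4e-04, and -0.748 without IWAT 1 and IWAT 2; Spearman rho = -0.846, permutation p = 8.8e-04, BH-adjusted p = 0.00176), so it does not single out adipocytes. With the score as a covariate the median size of the 2082 log2 fold changes went from 1.62 to 1.11 and the median SE from 0.38 to 0.44, 2 genes were called, and the cause was not tested.

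The same tests were run on other splits of the libraries. For BAT against white fat as 1 group, 4 of 100 splits drawn from 220 gave as many genes as the real 4, a share under 0.05 among the splits drawn. The larger counts were 154 (BAT 1, IWAT 1 and IWAT 2), 85 (BAT 1, BAT 3 and RWAT 1) and 27 (BAT 3, IWAT 2 and IWAT 3), which points to a structure of the samples other than depot. With only part of the 220 fitted, chance is not firmly excluded for this count. For its lists, 62 of 100 splits reached the real 16, with 27 as the highest other, so chance cannot be excluded. Pairs of depots have 10 splits, too few for a share under 0.05. Gene counts, with the highest other and the number of 10 splits as large, were 27 (0, 1) for BAT against EWAT. They were 5 (0, 1) against IWAT and 4 (22, 2) against RWAT, where the split with 22 set BAT 1, RWAT 1 and RWAT 3 apart. Of the 4 splits that part all 3 pairs of the same number, the highest other gave 0. They leave out the split with 22 and are too few to decide. For IWAT against EWAT the gene count was 2082 (0, 1). For RWAT it was 1 (0, 1) against EWAT and 0 (0, 10) against IWAT by edgeR. In that last pair 3909 genes had an unadjusted p below 0.05, DESeq2 called 1150 and limma-voom 0. List counts, with the highest other and the number of 10 splits as large, were 25 (23, 1) for IWAT against EWAT. For RWAT they were 23 (24, 2) against EWAT and 23 (22, 1) against IWAT.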
